A study of Homo sapiens with 8 samples.

How the data were processed

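The samples were Huh7 cells, a human hepatocellular carcinoma line, in which ARID1A had been knocked out and Flag-tagged ARID1A was then expressed from a lentivirus. ARID1A is a subunit of the SWI/SNF chromatin remodelling complex. The labels name 3 groups of Flag ChIP-seq libraries with 2 libraries each, wild-type ARID1A (WT), the V2084D mutant, and the V2084D mutant with knockdown of STUB1, a ubiquitin ligase that works with chaperones. They also name 2 WT input libraries, which were not analysed here as lists of their own. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The p-values of comparisons between libraries therefore measure only the spread between these libraries, which may be technical. The p-values of tests over genes or over regions hold no spread between libraries.

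The authors deposited 1 peak list per ChIP library, and the peak names in each list carry that library's name, so peaks were called per library and not on pooled reads. Per the submitters' processing notes the tools were Trimmomatic, Bowtie2, SAMtools, Picard, MACS2, bedtools and deepTools and the genome build was hg38. Versions, settings and the control given to each call are not given in the sources used here. Each list holds the fold enrichment of a peak (a ratio) as the authors' caller gave it, and the deposited significance values are −log10 p and −log10 q. The peak numbering in each list ran without gaps, and the lists reached q values just under 0.25. Fold, p and q were used only to describe, rank or filter peaks within 1 list. The read depth of the libraries is unknown from these files. The number of peaks in a list depends on depth and on the yield of the immunoprecipitation as well as on binding, and intervals printed here cover counting error only.

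Peaks of the 2 libraries of a group that overlapped by at least 1 bp were joined into reproducible regions. A region counted as covered by another library when one of its peaks overlapped a peak of that library by at least 1 bp. Peak numbers (log2), shares of WT regions covered and shares of peaks at gene ends were compared between groups by a two-sided exact permutation test of the libraries with Benjamini-Hochberg adjustment over the 3 group pairs for peak number and gene-end share. With 2 libraries against 2 there are 6 arrangements, and the smallest p that this test can give is 0.333, so no comparison of libraries by this test could pass 0.05. The WT fold enrichment of WT regions with a V2084D peak in both libraries and in neither was compared by a two-sided permutation test over regions with 100000 resamples. Confidence intervals (95%) are exact binomial for regained regions and Wilson for covered shares.

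Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the same assembly as hg38 on the assembled chromosomes. The table gives the start and end of each gene without its strand, its exons or its transcript starts. The planned distances to transcript starts were therefore measured to the nearer of the 2 annotated ends of a gene, and a share written as lying at gene ends counts summits within 1000 bp of either end of a protein-coding gene. Exon, intron and UTR positions were not used here. The planned search for sequence motifs at summits was not run, since no genome sequence was used here. There were 20037 protein-coding genes, and a gene counted as occupied when a region lay within 10000 bp of either end.

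The tests of 19 gene lists (544 names, all 544 matched) used Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. For loss, the background was the genes with a WT region. Genes are not replicates, and neighbouring genes can share a region. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per class of region, the 10 protein-coding genes within 10000 bp of the strongest regions, the strength being the worse of the ranks by −log10 q in the lists that define the class. It also took up to 4 members per gene list, those with the strongest WT regions, and ARID1A and STUB1. Some genes that the rule picked are not reported here. Other genes are named as members of the fixed lists.

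The scripts were tested on simulated data. A simulated covered share of 30.1% over 13542 regions was recovered as 30.1%, and 20 of 20 planted gene lists were found, while 10 of 200 random lists had p below 0.05 before adjustment. The planted lists were adjusted only among themselves, and both simulated V2084D lists kept the same regions. The simulation thus checks the code and not the power of the tests on the real lists. Alternatives were overlap of at least 50% of both peaks, summits within 200 bp, −log10 q of at least 5, fold enrichment of at least 5, lists of equal length (the strongest peaks by −log10 p, as many as the shortest list holds), assembled chromosomes alone, each library left out, the replicate number as a block, a gene-end window of 3000 bp, the ends of all genes, and link windows of 1000 and 50000 bp. Permutation tests of fold under alternatives used 10000 resamples. With a library left out, each peak of the other library of its group counted as a region, and that 1 library stood for both. After the data were seen, q under 0.05 and the lists without a block of chromosome 1 (29 to 56 Mb) were added, and peaks were counted in windows of 5 Mb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.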

Results

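Occupancy of chromatin by Flag-tagged ARID1A was mapped by ChIP-seq in ARID1A-knockout Huh7 cells that expressed the wild-type protein, the V2084D mutant, or the mutant together with STUB1 knockdown, with 2 libraries in each of the 3 groups. The lists held 27587 and 26515 peaks for WT, 6000 and 12384 for V2084D, and 8904 and 6663 for V2084D with STUB1 knockdown. The peaks covered 18.1 and 16.7 Mb in WT, 2.80 and 6.20 Mb in V2084D, and 4.69 and 3.22 Mb with STUB1 knockdown. Read depth is unknown for all 6 libraries. The lists do not measure the amount of ARID1A or STUB1 protein.

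The WT libraries show where the wild-type protein was found. HOX genes and genes of basic cell functions, such as those of ribosomal proteins and of the cell cycle, mostly carried WT regions, whereas genes of differentiated hepatocytes mostly did not. A reproducible WT region lay within 10 kb of an annotated end of 12325 of the 20037 protein-coding genes (61.5%). HOX genes, which pattern the body axis, were occupied at 37 of 39 members (adjusted p = 2.82e-05 by Fisher's exact test), and genes of cytosolic ribosomal proteins at 37 of 40 (adjusted p = 8.04e-05). Neighbouring HOX genes shared regions, such as HOXD10, HOXD11 and HOXD12, so the HOX members were not independent and their p-value is too small. By contrast, by the same Fisher's exact test, only 7 of 30 genes for proteins that hepatocytes secrete (adjusted p = 0.000124) and 6 of 28 hepatocyte metabolism genes (adjusted p = 9.14e-05) were occupied. Within the secreted list APOA1 and APOC3 shared a region, so its members were not all independent either. ALB (albumin), AFP, TTR, SERPINA1 and the fibrinogen genes FGA, FGB and FGG had no reproducible WT region within 10 kb, nor had the hepatocyte metabolism genes CPS1, CYP3A4, PCK1 and TAT.

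Other lists above the background in WT by Fisher's exact test were p53 targets (24 of 25, adjusted p = 0.000312), cell cycle and replication genes (28 of 30, adjusted p = 0.000312), TGF-beta response and EMT genes (26 of 28, adjusted p = 0.000708), chaperones and ubiquitin ligase partners (23 of 25, adjusted p = 0.00297) and the SWI/SNF subunits themselves (25 of 28, adjusted p = 0.00305). Receptor tyrosine kinase and MAPK feedback genes (26 of 30, adjusted p = 0.00715), oxidative phosphorylation genes (28 of 34, adjusted p = 0.0173) and the AP-1 family (15 of 17, adjusted p = 0.0306) were also above it by this exact test. Interferon and antigen presentation genes (11 of 30, adjusted p = 0.0111), fibroblast and endothelial markers (8 of 24, adjusted p = 0.0093) and olfactory receptors (0 of 32, adjusted p = 9.82e-13) were below it by the exact test. Liver transcription factors (18 of 24, adjusted p = 0.242), YAP/TAZ targets and TEADs (22 of 31, adjusted p = 0.376), blood cell markers (12 of 25, adjusted p = 0.242) and neuron markers (13 of 24, adjusted p = 0.53) did not pass the exact test. Among liver regulators, CEBPA, FOXA1, FOXA3, GATA4, GATA6 and PPARA had a WT region within 10 kb of an annotated end, and HNF4A and FOXA2 had none there. Regions farther inside a gene were not counted.

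The strongest WT regions at list members included that of MCM7, a subunit of the replicative helicase, on chromosome 7 from 100100235 to 100102590 (hg38), with fold enrichments of 11.9 and 10.7 in the 2 WT lists. The region at VIM, the gene of the mesenchymal filament protein vimentin, lay on chromosome 10 from 17228176 to 17230919 with 9.65 and 8.82. That at BCL7B, a SWI/SNF subunit gene, lay on chromosome 7 from 73556792 to 73558144 with 10.7 and 10.8. The neuronal gene ELAVL3 had a region with 13.5 and 16.3 on chromosome 19 from 11481329 to 11483101. Under the alternatives, the call of oxidative phosphorylation genes and that of the AP-1 family were each lost in 7 of 16 settings, that of the kinase feedback genes in 6, those of TGF-beta response and EMT genes and of fibroblast and endothelial markers in 5, that of cell cycle genes in 4, those of chaperones and p53 targets in 3, and those of SWI/SNF subunits, interferon genes and hepatocyte metabolism in 2. Those of HOX genes, ribosomal protein genes, hepatocyte secreted proteins and olfactory receptors were lost in none.

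**Figure D1:**
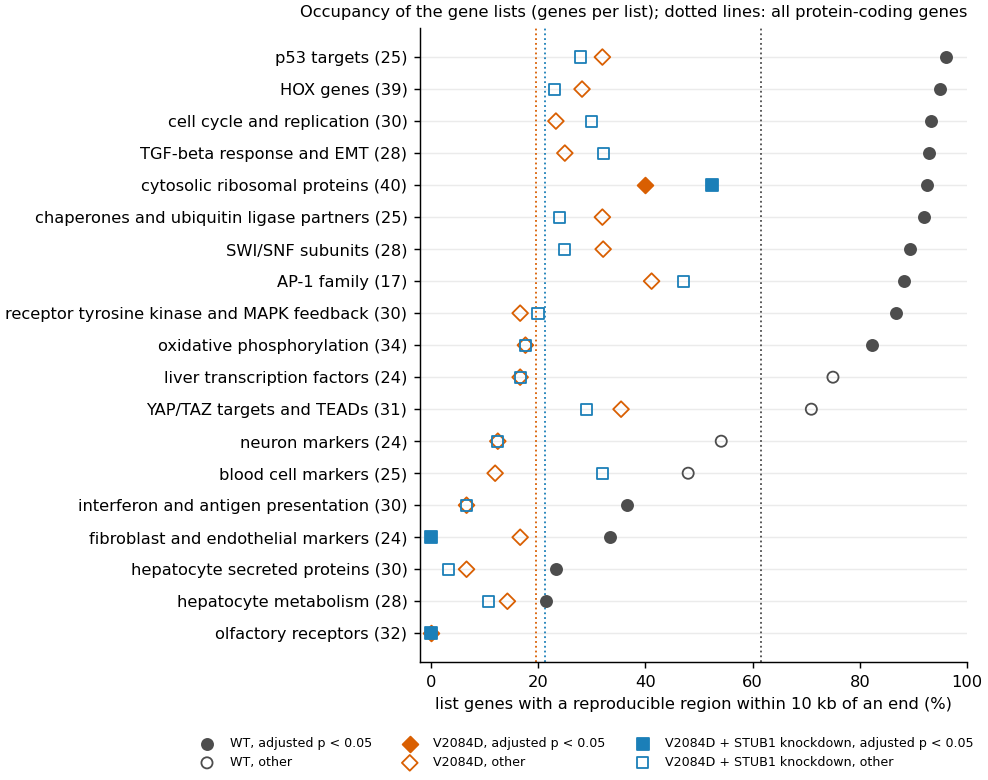
Share of the genes of each fixed list (percent, x axis, list size in brackets) with a reproducible region within 10 kb of an annotated end, for WT (grey circles), V2084D (orange diamonds) and V2084D with STUB1 knockdown (blue squares). Filled symbols passed the adjusted Fisher's exact test within their group, and dotted lines mark all protein-coding genes, 61.5% for WT, 19.7% for V2084D and 21.3% with STUB1 knockdown.

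The comparison of V2084D with WT asked how the mutation alters ARID1A occupancy. V2084D libraries held fewer peaks than WT, and the stronger a region was in WT, the more often it had a V2084D peak, as shorter lists of the same sites can also show. On average 9192 ± 4514 peaks (SD, n = 2) were listed for V2084D against 27051 ± 758 (SD, n = 2) for WT, and the log2 ratio of the geometric means was -1.65, or 3.14-fold fewer. The strongest WT regions without any V2084D peak lay at CFAP20 and RSRC2. Those at the chromatin regulators KDM5A, a histone demethylase, and RYBP and BMI1, both Polycomb genes, followed, and no gene list of Polycomb proteins or histone demethylases was tested. Of the 28 cell cycle and replication genes with a WT region, 15 had no V2084D peak within 10 kb, among them CCNB1, CDC6, MCM6 and MKI67, while CCND1, CDC20, MCM3 and MCM7 had one in both V2084D libraries, and the list did not pass the exact test of loss (adjusted p = 0.0933). The excess of this list over other genes ran from 2.43 to 27.1 percentage points in the settings that kept all libraries. With a library left out it ran from 6.95 to 25.7. The regions with a peak in all 6 libraries included those of KMT2A, a histone methyltransferase gene, and NELFB, a gene of the negative elongation factor. The ratio of the peak numbers lay between -2.20 and -1.10 (log2) over the 4 pairs of libraries. The exact permutation p was 0.333 (adjusted p = 0.5), and 0.333 is the smallest this test can give with 2 libraries per group.

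**Figure D2:**
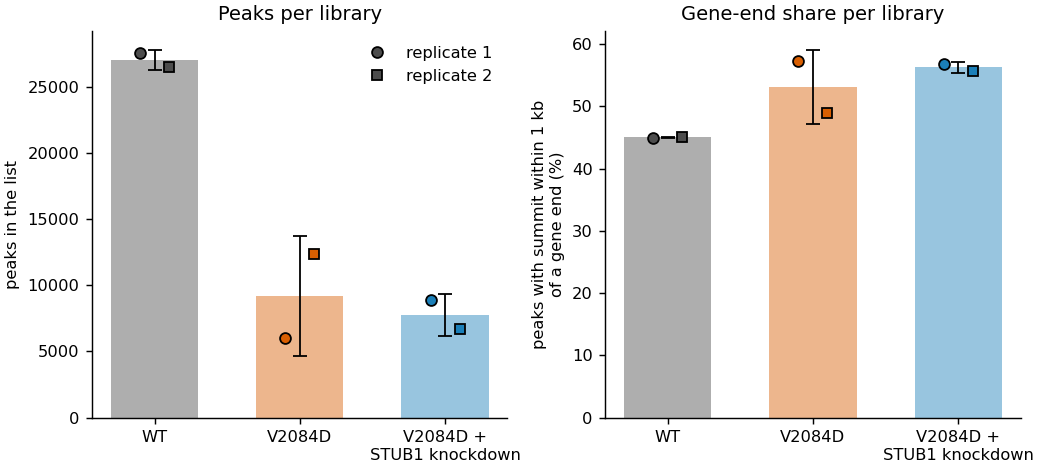
Left, peaks listed per library (y axis, number). Right, share of peaks (percent) with the summit within 1 kb of an annotated end of a protein-coding gene. Bars are group means of 2 libraries, error bars are SD, and the circle and square mark replicates 1 and 2. WT lists hold 26515 to 27587 peaks and mutant lists 6000 to 12384.

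Reproducible regions numbered 16157 in WT and 3617 in V2084D. V2084D peaks covered 27.7% (replicate 1, 95% Wilson interval 27.0 to 28.4%) and 46.8% (replicate 2, 46.0 to 47.6%) of the WT regions. Of the V2084D regions, 95.6% and 94.3% overlapped a peak of WT replicates 1 and 2. No V2084D peak was found at 7568 WT regions (46.8%), and both V2084D libraries had a peak at 3445 (21.3%). Regions kept in both V2084D libraries had been stronger in WT, with a median fold enrichment of 6.39 against 4.61 for the lost regions in WT replicate 1 and of 5.97 against 4.39 in replicate 2 (permutation p = 1e-05 in each, the smallest the resamples can give). A shorter list of the same sites can keep the stronger regions too, so this test does not tell altered binding from shorter lists. With WT regions split into 10 bins of equal size by strength, 68.1% and 84.8% of the strongest bin were covered by the V2084D libraries, and of the weakest bin 9.10% and 21.2%.

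**Figure D3:**
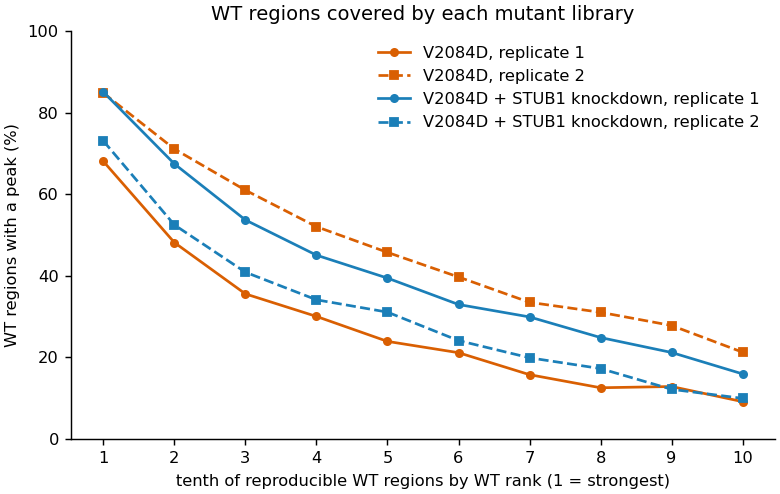
Share of reproducible WT regions (percent, y axis) with a peak in each of the 4 mutant libraries, by 10 bins of the regions ordered by the worse of their 2 WT ranks (x axis, 1 is the strongest). Orange, V2084D, and blue, V2084D with STUB1 knockdown, with replicate 1 as solid and replicate 2 as dashed lines. Coverage falls in every library, from 68.1% to 85.1% in the strongest bin.

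The strongest WT regions without a V2084D peak lay at CFAP20 (chromosome 16 from 58128426 to 58130098, WT folds 10.3 and 10.7), RSRC2 (chromosome 12 from 122526316 to 122527584, 9.62 and 8.60) and KDM5A (chromosome 12 from 388987 to 389927, 8.79 and 8.80). RYBP (chromosome 3 from 72447168 to 72448057, 10.4 and 10.3) and BMI1 (chromosome 10 from 22320225 to 22321632, 9.27 and 9.09) followed, and the other genes of this class were DERL2, CHAMP1, TNRC18, MTURN and ATF7IP. The summits of all but RYBP and TNRC18 lay within 261 bp of an annotated gene end. Regions strong in all 6 lists lay at TXLNA, H3-3A, EEF1A1, KMT2A, EAPP, ZMPSTE24, AIMP2, LOC124903857 and NELFB. At KMT2A (chromosome 11 from 118434547 to 118437985) the folds within the lists were 14.0 and 17.3 in WT, 9.85 and 12.6 in V2084D, and 13.7 and 15.5 with STUB1 knockdown. TXLNA and ZMPSTE24 lie in a block of chromosome 1, from 29 to 56 Mb, that held 2.03% and 2.08% of the WT peaks but 7.50% and 7.23% of the V2084D peaks and 5.99% and 6.97% of the peaks with STUB1 knockdown. It was not the only such stretch. Of 304 windows of 5 Mb with a mean of at least 30 WT peaks, 9 had a log2 excess over 1 in each mutant library, 5 of them in this block, and the others on chromosome 1 from 225 to 230 Mb, where H3-3A lies, and from 235 to 240 Mb, and on chromosome 6 from 0 to 5 and from 5 to 10 Mb. The window from 225 to 230 Mb held 0.503% and 0.530% of the WT peaks, 2.08% and 1.67% of the V2084D peaks and 1.38% and 1.77% with STUB1 knockdown.

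New sites were few among the reproducible V2084D regions. Only 84 of the 3617 V2084D regions (2.32%) had no peak in either WT library, and 31 of the 84 had a peak in at least 1 STUB1 knockdown library. The strongest of them lay near KPNA3, an importin gene (chromosome 13 from 49799458 to 49799951, V2084D folds 6.56 and 6.82), SENP3, AGPAT2, RAD54L and TGFB1I1, and others were LAPTM5, SLC2A1, C4B_2 and USP17L18. Of these genes, RAD54L, LAPTM5 and SLC2A1 lie in the chromosome 1 block, as did 21 of the 84 regions. The gene table places C4B_2 on chromosome 6 far from the other complement C4 genes, and its link to a region rests on that position.

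By gene list, cytosolic ribosomal protein genes stood above the background in V2084D (16 of 40 against 19.7% of other genes, adjusted p = 0.0392 by Fisher's exact test). RPS2, RPL12 and RPL8 had a peak in both V2084D libraries, and this call was lost in 6 of 16 alternative settings. Olfactory receptors were below it (0 of 32, adjusted p = 0.0258 by the exact test), a call also lost in 6 of 16 settings. The other 17 lists did not pass the exact test in V2084D, with 7 of 17 members for the AP-1 family (adjusted p = 0.277), 11 of 31 for YAP/TAZ targets and TEADs (adjusted p = 0.246) and 2 of 30 for hepatocyte secreted proteins (adjusted p = 0.277). The number of lists that passed was 11 without V2084D replicate 1 and 3 without replicate 2. In these settings each peak of the other V2084D library counted as a region. Among the genes with a WT region, 3444 of 12325 (27.9%) had no V2084D peak within 10 kb. No list differed from this share after adjustment. By Fisher's exact test the nearest was cell cycle and replication (unadjusted p = 0.00491), followed by TGF-beta response and EMT genes, such as FN1, SPARC, TNC and ZEB1, and receptor tyrosine kinase and MAPK feedback genes (11 of 26 and adjusted p = 0.573 for each). AP-1 genes without one were 2 of 15 (adjusted p = 0.62, exact test), ATF3 and FOSL1, while FOS, JUN, JUNB and JUND had a peak in both V2084D libraries. The V2084D peaks at JUNB formed no reproducible region, unlike those at FOS, JUN and JUND.

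Of all peaks, 44.9% and 45.1% in WT and 57.4% and 48.9% in V2084D had the summit within 1 kb of a gene end, a difference of 8.12 percentage points (pairs from 3.78 to 12.5, exact permutation p = 0.333). The direction turned when lists of equal length were compared, with -9.58 percentage points, and with peaks of −log10 q of at least 5, with -2.09. Within WT regions, those at gene ends were covered at 32.2% and 52.3% by the V2084D libraries and those over 10 kb away at 21.3% and 37.6%. Averaged over the 10 bins of WT strength these shares were 29.3% and 49.0% against 24.6% and 41.9%.

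The targeted and introduced genes themselves were looked at in every list. ARID1A, on chromosome 1, had a peak close to its high-coordinate end in each list, and in both V2084D lists this was the strongest peak of the genome, at 26779204 to 26780830 in replicate 1 and at 26779440 to 26780865 with a fold of 32.3 in replicate 2. It ranked 483 and 55 in the WT lists and 5 in each list with STUB1 knockdown. At EEF1A1, the gene of a translation elongation factor on chromosome 6, a peak from 73520051 to 73521358 in WT replicate 1 ranked 59, and its counterparts ranked 68 in WT replicate 2, 2 and 3 in V2084D, and 2 and 1 with STUB1 knockdown. STUB1, on chromosome 16, had peaks in all 6 lists, the best ranking 5141 and 769 in WT, 567 and 367 in V2084D, and 1430 and 4334 with STUB1 knockdown.

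**Figure D4:**
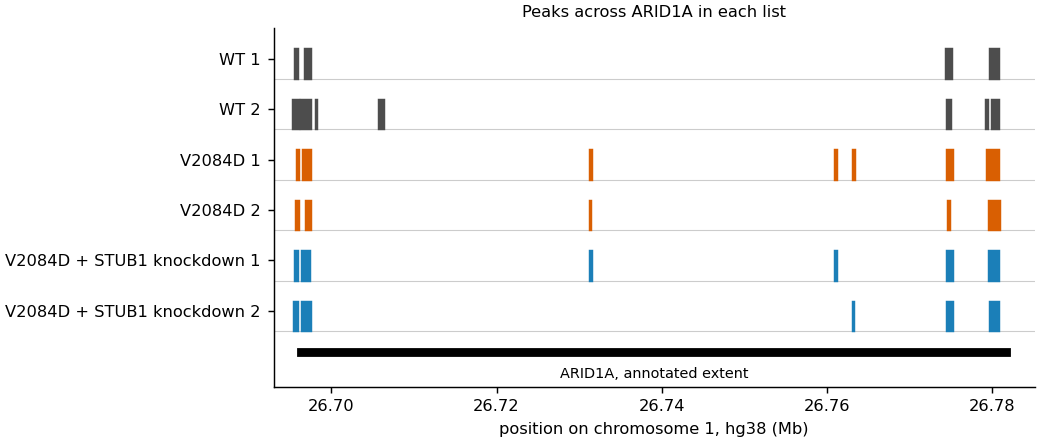
Peaks of each list across ARID1A on chromosome 1 (position in Mb, hg38, x axis), 1 row per library, with the annotated extent of the gene as a black bar. Each box spans a peak from its start to its end, and the boxes close to the high-coordinate end are the strongest peaks by −log10 q of both V2084D lists.

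The comparison of V2084D with and without STUB1 knockdown asked whether loss of this ligase restores occupancy by the mutant protein. Gains outnumbered losses with stricter peak thresholds and with lists of equal length, but both were about equal in number in the lists as deposited. At 398 WT regions without a V2084D peak both STUB1 knockdown libraries had a peak, among them regions at INO80B, a chromatin remodeller subunit gene, and at RYBP. The opposite pattern, a peak in both V2084D libraries and in neither knockdown library, was found at 436 WT regions. The liver regulators FOXA1 and GATA4 had no V2084D peak within 10 kb and a peak in both knockdown libraries. They were among 13 members of the gene lists with a WT region and this pattern, the others being ASS1, ATF3, VGLL4, PMEPA1, DPF1, CDK1, CDK2, RPL11, NDUFV2, DUSP6 and CD14. The 6 members with the opposite pattern were HSPA5, RRM2B, COX6C, NDUFV1, KDR and ROBO4, and the balance of these counts was not tested. At GATA4, PMEPA1, DPF1, CDK2 and NDUFV2 the peaks of the 2 knockdown libraries formed no reproducible region within 10 kb. The same held for the V2084D peaks at RRM2B. Over all genes with a WT region the opposite pattern was the more frequent, at 362 genes against 261.

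The regained regions made up 5.26% of the 7568 WT regions without a V2084D peak (95% exact interval 4.77 to 5.79%), and the opposite pattern 5.38% of the 8110 without a knockdown peak (4.90 to 5.89%). Regained regions were 47.7% of both patterns (44.3 to 51.2%). The STUB1 knockdown libraries covered 41.5% and 31.5% of the WT regions, a mean of 36.5% ± 7.12 (SD, n = 2) against 37.2% ± 13.5 (SD, n = 2) for V2084D. The difference of -0.73 percentage points (pairs from -15.3 to 13.9) was smaller than the spread between libraries (exact permutation p = 1). It became positive in 5 alternative settings that kept all libraries, up to 5.44 percentage points for peaks of −log10 q of at least 5 (exact permutation p = 0.667), where 72.2% of both patterns were regained regions. Without V2084D replicate 1 the regained share was 23.3%, and without replicate 2 of the knockdown it was 66.8%. Which pattern was the more frequent thus changed with the library left out. The rule changed too, since 1 library then stood for its group.

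Peaks numbered 7784 ± 1585 (SD, n = 2) with STUB1 knockdown, a log2 ratio of -0.16 to V2084D (pairs from -0.89 to 0.57, exact permutation p = 1) and of -1.81 to WT (pairs from -2.05 to -1.57, exact permutation p = 0.333, adjusted p = 0.5). The groups had 3966 reproducible regions with knockdown and 3617 without. Of the regions with knockdown, 96.7% and 95.1% overlapped a peak of WT replicates 1 and 2. In all, 5642 WT regions (34.9%) had no peak in any of the 4 mutant libraries and 2108 (13.0%) had one in each. The gene-end share was 56.9% and 55.7% with knockdown, 3.15 percentage points above V2084D (exact permutation p = 1) and 11.3 above WT (exact permutation p = 0.333), the latter turning to -8.96 with lists of equal length.

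Strong regained regions lay at INO80B (chromosome 2 from 74454477 to 74455334, folds 6.93 and 6.06 in the knockdown lists), DDX11 (chromosome 12 from 31073329 to 31074621, 5.38 and 5.11) and ZNF780A (chromosome 19 from 40090446 to 40091331, 5.43 and 4.66). Others of this class lay at RBM25, RYBP, NBPF11, PPP1R3B and PDCD10. At RYBP the folds were 6.05 and 4.89. Of the 3444 genes with a WT region and no V2084D peak, 261 (7.58%) had a peak in both knockdown libraries, against 362 of 4035 (8.97%) for the opposite pattern. No gene list differed from other genes in this share after adjustment, the nearest by Fisher's exact test being the liver transcription factors with 2 of 6 (FOXA1 and GATA4, unadjusted p = 0.07, adjusted p = 0.924).

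With STUB1 knockdown, cytosolic ribosomal protein genes were again above the background (21 of 40 against 21.2% of other genes, adjusted p = 0.000258 by Fisher's exact test), with RPS2, RPL8 and RPL12 among them. Fibroblast and endothelial markers (0 of 24, adjusted p = 0.0312) and olfactory receptors (0 of 32, adjusted p = 0.00734) were below it by the exact test, but the first call was lost in 9 and the second in 6 of 16 settings. Without replicate 1 or without replicate 2 of the knockdown, 7 lists passed instead of 3, with each peak of the other knockdown library counted as a region. The AP-1 family (8 of 17, adjusted p = 0.0602) and hepatocyte secreted proteins (1 of 30, adjusted p = 0.0587) did not pass the exact test, and whether any list differed between the knockdown and V2084D groups was not tested.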

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

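Peaks on unplaced, random or alternate sequences entered no link to genes and are listed here as a signal outside the comparisons, with 541 and 476 peaks in WT, 123 and 215 in V2084D, and 145 and 124 in V2084D with STUB1 knockdown. Of the 3 such sequences with the most peaks, the random sequence KI270733v1 of chromosome 22 held 25 and 22 peaks in WT, 28 and 23 in V2084D, and 29 and 28 with STUB1 knockdown. The alternate sequence KI270905v1 of chromosome 15 held 25 and 28, 4 and 11, and 8 and 4, and the random sequence GL000225v1 of chromosome 14 held 16 and 19, 16 and 24, and 3 and 6. The tests of other sites, of loss through STUB1 and of the 2 ends of ARID1A below were chosen only after the result was seen, and the chromosome 1 block and the windows of 5 Mb were chosen on the data.

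The smaller number of peaks in the mutant lists could come from shorter lists of the same sites, through lower depth or enrichment. Among the strongest peaks, as many per list as the shortest list holds, WT lists overlapped mutant lists by 47.9% ± 2.06 (SD over 8 pairs of lists) and mutant lists each other by 47.4% ± 2.38 (SD over 6 pairs), a difference of 0.493 percentage points, which the explanation allows, although the WT lists overlapped each other by 60.3%. At this length the gene-end share differed by -9.58 percentage points (V2084D minus WT) and -8.96 (knockdown minus WT). Whether shorter lists of the same sites could give this difference was not tested. The tables argue against binding of other sites as the cause, since V2084D regions lacked a peak of WT replicate 2 in 5.70% of cases, 3.79 percentage points above the 1.91% for the strongest WT replicate 1 peaks, and a peak of either WT library in 2.32%. Loss of the mutant protein through STUB1 could not be told from no effect, with -0.730 percentage points between knockdown and V2084D. Read counts of the libraries and protein levels would separate lower depth from lower binding.

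The excess of mutant peaks on chromosome 1 from 29 to 56 Mb was 1.75 ± 0.14 (log2, SD over 4 libraries). It was 2.13 among peaks over 10 kb from any gene end, as extra DNA copies in the mutant cells could give, but copies in all lines could give the same. More copies in all lines stayed open, since block peaks had a higher −log10 q than peaks of like fold in WT (median percentiles 66.8 and 66.9) and in 3 mutant lists (62.5, 66.8 and 61.3), but hardly in V2084D replicate 2 (51.9, against 51.1 on chromosome 2 and 35.5 on chromosome 1 left of the block). An excess at gene ends that was -0.72 (log2) relative to distal peaks spoke against a mutant protein drawn to genes of the block. The WT inputs would test only copies in the WT line, and DNA of the mutant cells would be needed for the rest.

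The strong mutant peaks at the high-coordinate end of ARID1A and at EEF1A1 may come from vector DNA that carries parts of these genes. Where a list held at least 10 peaks of like fold, both had a −log10 q at or above the percentile 98.5 of those peaks, but the high ranks for which these loci were picked largely fixed this outcome, so it does not support the explanation, which stays open. Binding to both ends of ARID1A alike was not seen, since the best peak at the low-coordinate end ranked at least 83.6 times lower in each mutant list. In the WT lists it ranked 15.8 and 57.2 times lower, so the difference was not particular to the mutant lists. Inside the gene, peaks near 26774278 lay in all 6 lists. A peak from 26731156 to 26731520 in V2084D replicate 1 had counterparts in V2084D replicate 2 and knockdown replicate 1 but in no WT list. Exon positions were not used, so these peaks were not weighed for the vector explanation. The sequence of the vector would help to decide it.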

How the results depend on the processing

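The number of peaks fell from WT to both mutant groups in the settings in which it was compared (−log10 q of at least 5, fold of at least 5, q under 0.05, assembled chromosomes, without the chromosome 1 block, the replicate block and each library left out), while the balance of V2084D with and without STUB1 knockdown depended on the setting. Values were counted as the same within 1.5 times for counts, within the SD between libraries for mean coverage (13.5 points for V2084D, 7.12 with knockdown), within the interval for the regained share, and on the same side of 0 and of the threshold for tested values, so that large shifts can count as the same. By this rule, of 300 values of the main results under alternatives 223 stayed the same, 60 moved and 17 turned direction, and of 336 values of single gene lists 261 stayed the same, 75 became weaker and 0 turned. For the values that moved or turned the cause was not tested. Depth is unknown, so how far it limits the shorter mutant lists could not be measured. The motif alternatives were not run, since the motif search itself was not run.

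With −log10 q of at least 5, the log2 ratio of peak numbers of knockdown to V2084D was 0.31, the gene-end share of V2084D minus WT was -2.09 percentage points, and regions numbered 6153 in WT, 664 in V2084D and 987 with knockdown. Mean coverage of WT regions was 20.2% for V2084D and 25.6% with knockdown (difference 5.44), regained regions numbered 190, or 72.2% of both patterns, and 9, 0 and 0 lists passed in WT, V2084D and knockdown. With fold of at least 5 the log2 ratio was 0.12, the gene-end share differed by -0.130 (knockdown minus WT) and -0.409 (knockdown minus V2084D), and regions numbered 5416, 705 and 918. Coverage was 22.7% and 26.1% (difference 3.34), regained regions numbered 157 (64.9%), and 4, 0 and 0 lists passed. With lists of equal length the gene-end share differed by -9.58 (V2084D minus WT) and -8.96 (knockdown minus WT), WT regions numbered 3540, coverage was 56.9% and 60.5% (difference 3.56), regained regions numbered 143 (60.9%), and 6, 0 and 1 lists passed.

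With overlap of at least 50% of both peaks, regions numbered 11848 in WT, 2398 in V2084D and 2820 with knockdown, coverage was 23.9% and 24.9% (difference 0.992), the regained share was 57.2%, and 10, 0 and 1 lists passed in WT, V2084D and knockdown. With summits within 200 bp the difference was 1.10 and the regained share 54.3%, and 8, 0 and 1 lists passed in WT, V2084D and knockdown. The link window of 1000 bp left 1 list in V2084D and 1 with knockdown, and that of 50000 bp gave 4 and 5. Without the chromosome 1 block, added after the data were seen, 1 list passed in V2084D, and with q under 0.05 no main result moved beyond the tolerances above. With knockdown, ribosomal protein genes held in 14 of 16 and fibroblast and endothelial markers in 7, and olfactory receptors held in 10 of 16 there and in V2084D.

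With each library left out in turn, the log2 ratio of peak numbers ran from -2.17 to -1.13 (V2084D to WT), -2.02 to -1.60 (knockdown to WT) and -0.69 to 0.36 (knockdown to V2084D). The gene-end differences ran from 3.88 to 12.4, 10.7 to 11.9 and -1.09 to 7.39. Coverage ran from 24.4% to 46.8% (V2084D) and 23.7% to 41.5% (knockdown), its difference from -10.3 to 8.82. The regained count ran from 454 to 1424 and its share from 23.3% to 66.8%. The median fold of kept minus lost regions ran from 1.10 to 2.02 (WT replicate 1) and 1.02 to 1.86 (replicate 2). Regions ran from 16157 to 27587 (WT), 3617 to 12384 (V2084D) and 3966 to 8904 (knockdown), and lists passing from 13 to 15, 2 to 11 and 3 to 7, with 0 to 0 for loss. In each of these settings 1 library stood for its group without an overlap filter. The upper numbers of regions are therefore the peak numbers of single lists. With the replicate number as a block, the log2 ratio of V2084D to WT was again -1.65 (exact sign flip p = 0.5, the smallest possible). Libraries of the same number deviated together in 1 of 3 group pairs, which with 2 libraries per group decides nothing about a pairing.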

Other observations

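Regions lay near genes of tRNAs in the mutant lists more often than near protein-coding genes. The gene classes here were chosen only after the result was seen, and no test was made of them. Of 443 tRNA genes, 244 had a WT region within 1 kb (55.1%), 126 a V2084D region (28.4%) and 160 a region with STUB1 knockdown (36.1%). The protein-coding genes had one in 10300 cases in WT (51.4%), 2791 in V2084D (13.9%) and 2967 with knockdown (14.8%). The 184 WT regions near tRNA genes, 38 of them on chromosome 1, were covered at 51.1% and 59.8% by V2084D and at 68.5% and 63.6% with knockdown, against 32.5%, 51.7%, 47.0% and 36.6% for other WT regions in the same bins of WT strength. The 67 WT regions near small nuclear RNA genes, 26 of them on chromosome 1, did not all lie on the same side, with 56.7% and 61.2% for V2084D and 71.6% and 70.1% with knockdown against 46.9%, 65.6%, 62.5% and 50.9%. Of the 22 WT regions near ribosomal RNA genes 19 were in the strongest bin and 9 on chromosome 1. Their coverage was 90.9% and 95.5% for V2084D and 95.5% and 86.4% with knockdown against 62.6%, 80.0%, 79.4% and 67.4%. The excess of mutant peaks on parts of chromosome 1 was not taken out of these shares.

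In replicate 2 of the knockdown, peaks inside NOTCH1, a receptor gene, on chromosome 9 (hg38) from 136496949 to 136497677 and from 136495963 to 136496409 had folds of 21.8 and 22.8, with no peak there in any other list. A peak inside USP43 on chromosome 17 from 9701325 to 9701730 was found in V2084D replicate 1 alone (fold 7.82), and 1 inside STOX1 on chromosome 10 from 68828105 to 68828648 in WT replicate 1 alone (fold 9.81). Peaks without a counterpart in any other list made up 30.8% and 28.7% of the WT lists, 9.02% and 19.4% of the V2084D lists, and 5.79% and 5.61% of the knockdown lists. The WT lists were much longer than the others, and list length was not taken out of these shares.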
